A study of Mus musculus with 24 samples.

How the data were processed

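RNA from the frontal lobe of 24 mice was measured on Affymetrix mouse genome arrays, 1 array per mouse. The labels assign 6 mice to each of 4 groups. These are knockouts of Arg1 (KO), knockouts given a viral treatment (TR), heterozygotes (HE) and wild types (WT). The extraction protocol speaks of animals at postnatal day 14, while the labels of the single samples also list days 13 and 15. Per the labels' protocols, total RNA was treated with DNase, amplified from an oligo(dT) primer into biotin-labelled cRNA and hybridized. Priming from the poly(A) tail makes the values those of the 3' ends of polyadenylated transcripts.

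The deposited table holds 1 log2 value per Ensembl mouse gene and array, for 18057 genes. Per the submitters' processing notes the tools were affy and RMA, a method that corrects background, makes the distributions of the arrays equal and summarizes the probes of a feature. Versions, the map from probes to genes and any later step are not given in the sources used here. The array medians lay between 6.71 and 6.79 and the interquartile ranges between 3.54 and 3.72, so the arrays shared 1 scale to within small differences. Probes that cross-hybridize or lie outside an altered part of a transcript would not be visible in a value per gene.

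The labels give 3 batches, called batch 1, 2 and 3 here. Batch 1 held 3 KO and 3 WT arrays and batch 2 held 3 HE and 3 TR arrays, in each case 1 per group at postnatal days 13, 14 and 15. Batch 3 held 3 arrays of each of the 4 groups, all at day 14. In batch 3 the titles of the KO samples start with other letters than those of the other groups, and the labels do not say what the letters mean. The means of a gene over the batches were nearly equal. A median difference of 0.010 log2 between batch means was found where the spread between arrays alone would give 0.036, and 1.04% of genes had an unadjusted batch p under 0.05 where 5% would by chance. The deposited values therefore look adjusted for batch without regard to group, a step that the labels do not name. Such an adjustment sets batch 1, in which 3 of the 6 arrays are KO, to the same level as batch 2, which holds no untreated knockout. Group means over all 6 arrays are then not comparable between groups that lie in different batches, so levels are given within a batch and differences come from a model with batch as a term.

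Each comparison was fitted with limma 3.58.1 in R 4.3.3 on the deposited log2 values, without a filter. The model held the 4 groups and the 3 batches as fixed terms over all 24 arrays, with an intensity trend in the empirical Bayes step. It had 18 residual degrees of freedom and a prior of 6.04. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 over the 18057 genes were called. The 5 comparisons were KO against WT, TR against KO, TR against WT, TR against HE and HE against WT. Only batch 3 holds both groups of TR against KO, TR against WT and HE against WT, and each comparison was also fitted within each batch that holds both of its groups. Replicate numbers follow the order of deposition. In batches 1 and 2 the arrays of both groups can be matched by postnatal day, which the labels do not tie to a shared litter or animal. Over all genes, the deviations of same-day arrays from their group means correlated at 0.042, -0.155 and 0.083 in batch 1 and at 0.216, 0.248 and 0.157 in batch 2, for days 13, 14 and 15. Arrays of different days correlated at -0.224 to 0.194 in batch 1 and at -0.249 to 0.022 in batch 2. All same-day values were thus above the others in batch 2 and not in batch 1, with no chance reference computed. Fits with batch and day as a block, a fit of batch 2 alone with day as a block, and a permutation of the score within same-day pairs of batch 2 were added as alternatives.

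A knockout signature score used separate arrays to choose and to measure genes. The 100 genes of highest and the 100 of lowest moderated t in KO against WT were chosen in batch 1 alone, among genes above the median mean. The score of an array in batch 2 or 3 was the mean log2 value of the first set minus that of the second. Scores were compared by exact two-sided permutation of group labels within batch. Intervals came from inverting that test over a grid of shifts, at 95% for TR against HE and at 90% for the comparisons of 3 arrays against 3, where no p below 0.1 can be reached.

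The fitting code was tested on simulated data for 18057 genes, with 100 genes shifted by 0.5 log2 and 100 by 1 log2. For KO against WT it called 88 and 98 of them, for TR against KO 83 and 99, for TR against WT 66 and 98, for TR against HE 91 and 99, and for HE against WT 83 and 99. False calls made up between 4.71% and 6.53% of all calls. The simulated noise was independent between genes. The shifted genes were drawn anew for each comparison, so the counts of calls also vary by the draw. Where few genes change, the adjusted threshold is stricter and fewer shifts of these sizes would be called. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.077 for KO against WT and TR against HE and 0.094 for the comparisons that span batches. Arrays of a group within a batch correlated at r of 0.989 to 0.997 over genes in 24 pairs. No pair shared more than 10 identical values, so none of these arrays was a copy of another. Each array was counted as 1 replicate, though the labels do not say whether animals shared a litter or origin.

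The table gives Ensembl gene IDs without names. The gene table at hand lists 49997 genes but no Ensembl IDs, so 0 of the 18057 IDs were matched and genes are printed by ID. For that reason 28 gene lists fixed before the data were examined, including cell type markers and pathways, were not evaluated, and the targeted gene was not looked up by name. The test design, the alternatives and the rule for naming genes were likewise fixed before the data were examined. The rule took, for KO against WT and TR against KO, the 8 highest and 8 lowest log2 differences among called genes with a mean above the median gene and the same sign in each batch holding both groups, and 4 each way for the other comparisons. Because the names are not paired, at most 2 IDs that rose and 2 that fell are printed. They are the highest and the 2 lowest by the rule in KO against WT, and 1 further gene chosen after its values were seen. The alternatives were other treatments of batch, age as a covariate, filters on dim genes, other settings of limma, further scaling of the arrays, and leaving out each array in turn. A covariate for sex and other rules for combining probe sets could not be run, the first because the marker gene was not identified by name and the second because the table holds 1 value per gene. Figures were drawn with Python 3.11.15.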

Results

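Arginase 1, encoded by Arg1, is the last enzyme of the urea cycle and splits arginine into ornithine and urea in the liver. The title of the study ties its deficiency to impaired myelination of the young brain. Expression was measured in the frontal lobe of 24 mice, 6 in each group. The groups were Arg1 knockouts (KO), knockouts given a viral treatment (TR), heterozygotes (HE) and wild types (WT). Array medians ranged from 6.71 to 6.79 log2, single values from 1.85 to 13.94, and the median gene had a mean of 6.77. Batch 1 held KO and WT, batch 2 held HE and TR, and batch 3 held all 4 groups, with 3 arrays per group in each.

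ENSMUSG00000019987 separated the WT arrays from all others, while HE and KO arrays overlapped in batch 3 (highest HE 6.89, lowest KO 6.87). In batch 3 its mean level was 4.35 ± 0.433 (SD, n = 3) in WT, 6.71 ± 0.261 in HE, 7.08 ± 0.283 in KO and 7.35 ± 0.113 in TR, on the log2 scale. In batch 1 it was 4.16 ± 0.296 in WT and 7.87 ± 0.071 in KO (SD, n = 3). In batch 2 it was 6.37 ± 0.042 in HE and 7.12 ± 0.080 in TR (SD, n = 3). The highest of the 6 WT arrays read 4.80 and the lowest of the 18 others read 6.33. This gene lies below the median mean, so the ranking part of the naming rule leaves it out, and it was chosen after its values were seen. A further part of the rule named Arg1 in every comparison and could not be applied without gene names. The files do not pair ENSMUSG00000019987 with a name, so whether it is the targeted gene was not established. Its differences can therefore not be read as a response to loss of the enzyme.

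**Figure D1:**
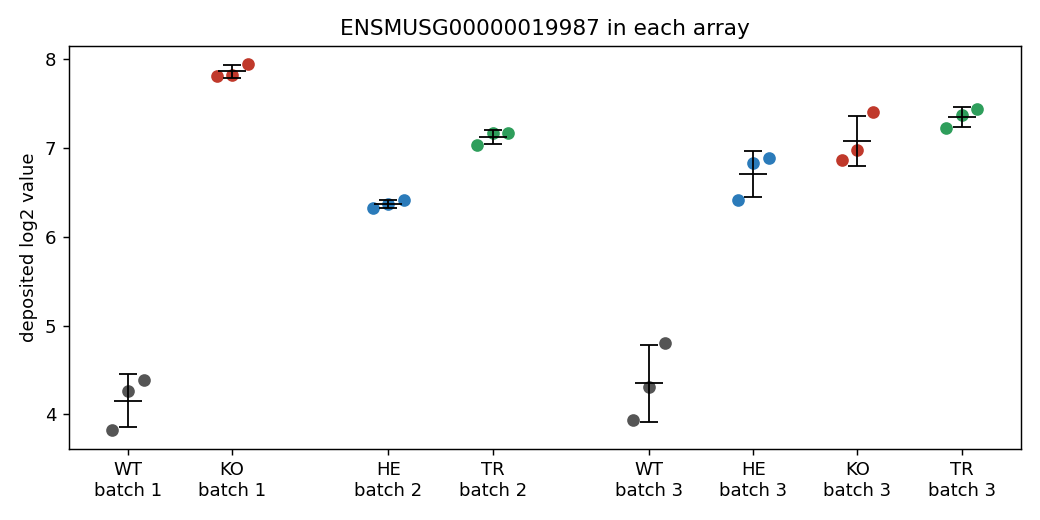
Deposited log2 value (vertical axis) of ENSMUSG00000019987 in each of the 24 arrays, by group and batch (horizontal axis). Points are arrays, long bars are means and whiskers are ± 1 SD of 3 arrays. The 6 WT arrays lie at or below 4.80 and the 18 other arrays at or above 6.33.

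The comparison of KO with WT asks what loss of the enzyme changes in the developing brain. ENSMUSG00000019987 was 9.32-fold higher in KO, a log2 difference of 3.22 ± 0.156 (SE, 6 arrays per group). ENSMUSG00000030711 was 3.15-fold higher, at 1.66 ± 0.196, and ENSMUSG00000044338 and ENSMUSG00000037071 were lower, at -1.46 ± 0.293 and -1.25 ± 0.168. Across the array 1439 of 18057 genes changed, 630 higher and 809 lower in KO. Most changes were small, with a median of 0.34 log2 among the genes that rose and -0.31 among those that fell. At least 1 log2 unit separated the groups for 22 genes that rose and 10 that fell.

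The limma adjusted p (Benjamini-Hochberg) was 1.51e-12 for ENSMUSG00000019987, 6.96e-06 for ENSMUSG00000030711, 0.00252 for ENSMUSG00000044338 and 3.43e-05 for ENSMUSG00000037071. ENSMUSG00000030711 differed by 1.69 in batch 1 and 1.63 in batch 3, ENSMUSG00000044338 by -1.49 and -1.42, and ENSMUSG00000037071 by -1.16 and -1.34. Within batch 1 alone 913 genes changed and within batch 3 alone 176, where ENSMUSG00000044338 had a limma adjusted p (Benjamini-Hochberg) of 0.161, the highest of 26 alternatives that started at 1.74e-05, and a KO spread of 1.38 log2 (SD, n = 3). The count was 904 with only the KO and WT arrays in the fit, 949 without WT replicate 6 and 925 without KO replicates 1 and 4, and the share of changed genes that were higher moved from 43.8% to 49.0% after renewed quantile normalization and to 54.1% after centring each array on its median.

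The genes called in batch 1 kept their direction in the separate animals of batch 3. Of the 406 genes higher in KO in batch 1, 364 (89.7%) were also above 0 in batch 3, and of the 507 lower genes 444 (87.6%) were below 0. Together 808 of 913 (88.5%) had the same sign, against 58.7% of all genes, and 96 genes were called in both batches. The sizes were smaller in batch 3, at a median of 0.27 log2 for the 406 higher genes, which stood at 0.54 in batch 1, and of -0.21 for the 507 lower genes, which stood at -0.50. Across all genes the differences in the batches correlated at Pearson r = 0.443 and Spearman rho = 0.298. Genes are not independent replicates, and genes chosen for a large value in one batch are bound to lie lower in another.

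The comparison of TR with KO asks what the viral treatment changes in knockout animals. ENSMUSG00000030711 was lower in TR than in KO, at -1.60 ± 0.240 log2 (SE, 6 arrays per group), and ENSMUSG00000037071 was higher, at 1.14 ± 0.206. Both, like ENSMUSG00000044338, were named as extremes of KO against WT over the same KO arrays, which favours an opposite sign here. ENSMUSG00000044338 measured 1.17 ± 0.359 higher and ENSMUSG00000019987 0.05 ± 0.191 higher, neither past the threshold. In batch 3 ENSMUSG00000030711 had a mean of 7.08 ± 0.352 in TR, 8.71 ± 0.536 in KO and 7.08 ± 0.283 in WT (SD, n = 3). ENSMUSG00000037071 had 10.26 ± 0.070 in TR, 9.02 ± 0.559 in KO and 10.35 ± 0.099 in WT (SD, n = 3).

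In all 561 genes changed between TR and KO, 294 higher and 267 lower in TR. The smallest limma adjusted p (Benjamini-Hochberg) of this comparison was 1.89e-08, in a gene not printed here. The limma adjusted p (Benjamini-Hochberg) was 0.000501 for ENSMUSG00000030711, 0.00261 for ENSMUSG00000037071, 0.0747 for ENSMUSG00000044338 and 0.927 for ENSMUSG00000019987. For ENSMUSG00000044338 the limma adjusted p (Benjamini-Hochberg) was 0.0401 with age as a covariate, 0.0466 with array weights and 0.00149 without KO replicate 3, where the difference was 1.67. It was 0.251 without KO replicate 1, where the difference was 0.76, and over 25 alternatives it ranged from 0.00149 to 0.482. For ENSMUSG00000037071 it was 0.0804 without a batch term, 0.209 with batch as a random block and 0.141 with only the TR and KO arrays, with a range of 8.46e-05 to 0.209 over 25 alternatives. For ENSMUSG00000030711 it was 0.155 with batch as a random block, with a range of 6.98e-05 to 0.155.

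Batch 3, the only one with both groups, gave 185 genes on its own, 89 higher and 96 lower in TR. The count was 28 without a batch term, 0 in limma with batch as a random block (1502 genes at an unadjusted p under 0.05, against 3210 with batch as a fixed term) and 31 with only the TR and KO arrays. It was 281 without KO replicate 1, 329, 278 and 369 without TR replicate 1, 2 and 3, and 297 without KO replicates 1 and 4. The share of changed genes that were higher in TR was 52.4%, and it was 46.6% after renewed quantile normalization and 45.6% after centring each array on its median.

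The genes that batch 1 set apart moved the other way between KO and TR in batch 3. The 406 genes higher in KO in batch 1 had a median TR minus KO difference of -0.27 log2 in batch 3, and 357 (87.9%) were below 0. The 507 genes lower in KO had a median of 0.21, and 433 (85.4%) were above 0. Against WT the same sets differed in TR by medians of -0.0050 and -0.0072. The KO and TR arrays of batch 3 had no part in choosing these genes.

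**Figure D2:**
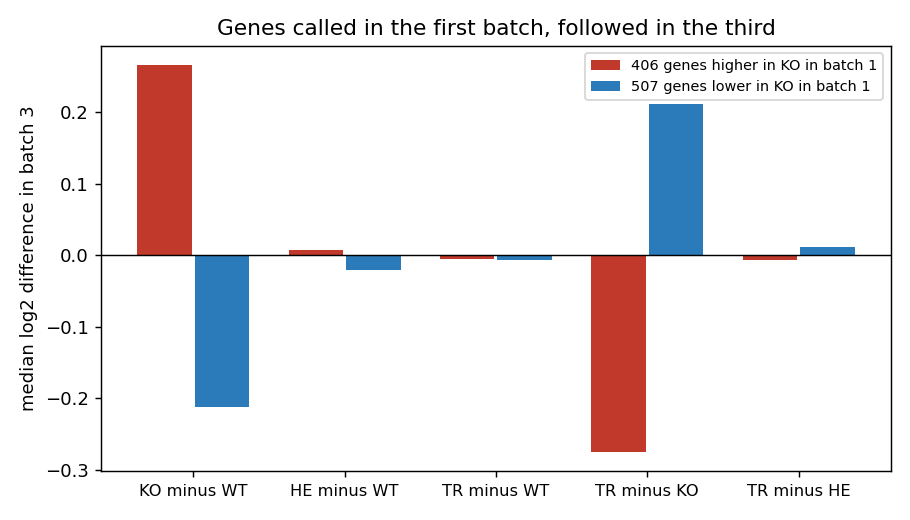
Median log2 difference in batch 3 (vertical axis) of the 406 genes higher and the 507 genes lower in KO in batch 1, for each of the 5 comparisons (horizontal axis). Bars are medians over genes and start at 0. They reach 0.27 and -0.21 for KO minus WT, -0.27 and 0.21 for TR minus KO, and between -0.021 and 0.011 for the other comparisons.

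The signature score, the mean log2 value of the 100 genes of highest moderated t in KO against WT in batch 1 minus that of the 100 of lowest, was 0.43 ± 0.358 in KO, -0.39 ± 0.086 in WT, -0.35 ± 0.131 in HE and -0.40 ± 0.082 in TR in batch 3 (SD, n = 3, log2). All 3 KO arrays lay above the 9 others. KO exceeded WT by 0.82 and TR lay below KO by -0.83, each with an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow, and 0.25 after Benjamini-Hochberg adjustment over 5 comparisons. The 90% intervals were 0.365 to 1.245 and -1.255 to -0.385. TR stood 102% of the way from KO to WT, with 96.2% to 107% when 1 array was left out, and 92.7% when all genes were weighted by their batch 1 difference. The range shows the weight of single arrays only, and an interval of this share was not computed.

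**Figure D3:**
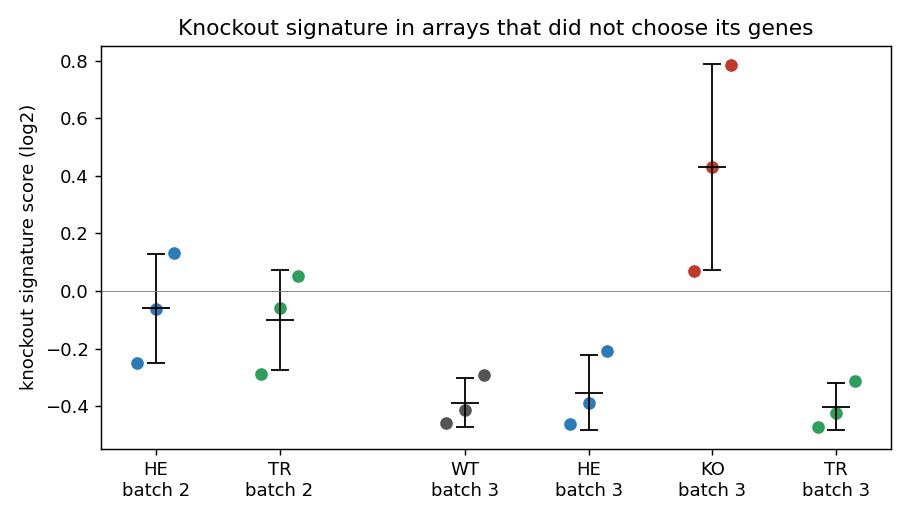
Knockout signature score in log2 units (vertical axis) of each array in batches 2 and 3, by group (horizontal axis), for genes ranked in batch 1. Points are arrays, long bars are means and whiskers are ± 1 SD of 3 arrays. In batch 3 the KO arrays range from 0.07 to 0.79 and the TR arrays from -0.47 to -0.31.

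The comparison of TR with WT asks what stays different in treated knockouts. ENSMUSG00000019987 was 9.65-fold higher in TR, at 3.27 ± 0.191 log2 (SE, 6 arrays per group), and was the only gene of 18057 that changed. ENSMUSG00000030711 differed by 0.06 ± 0.240, ENSMUSG00000044338 by -0.28 ± 0.359 and ENSMUSG00000037071 by -0.10 ± 0.206. The signature score of TR differed from that of WT by -0.015, with a 90% interval of -0.175 to 0.145. That interval excludes the difference of 0.82 between KO and WT.

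The limma adjusted p (Benjamini-Hochberg) was 1.04e-10 for ENSMUSG00000019987, and the next gene had 0.125. At an unadjusted p under 0.05, 1033 genes passed in limma, where chance gives 903. That number depended on single arrays. Leaving out 1 array at a time, it ran from 766 without TR replicate 1 to 1725 without TR replicate 3. For the score the exact permutation p was 0.7. The count of changed genes was 2 without a batch term and 2 without WT replicate 2, 5 with batch as a random block, and 0 in limma when the dimmer 50% of genes, among them ENSMUSG00000019987, were left out (486 at an unadjusted p under 0.05). Simulated shifts of 0.5 log2 were called in 66 of 100 genes here, with 100 further genes shifted by 1 log2, which loosens the adjusted threshold. With few changed genes fewer would be called, so changes of that size or less in single genes can be missed.

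TR and HE share 2 batches and differ in the number of functional alleles and in the treatment. In this model 0 genes changed between them, with 792 at an unadjusted p under 0.05 in limma where chance gives 903. Leaving out 1 array at a time, the latter number ran from 544 without HE replicate 5 to 1457 without TR replicate 3. ENSMUSG00000019987 was 0.70 ± 0.156 log2 higher in TR (SE, 6 arrays per group), at 0.75 in batch 2 and 0.64 in batch 3. The signature score differed by -0.044, with a 95% interval of -0.225 to 0.145. In batch 2 the score was -0.06 ± 0.191 in HE and -0.10 ± 0.174 in TR (SD, n = 3). The 406 genes higher in KO in batch 1 differed between TR and HE by a median of -0.053 log2 in batch 2 and -0.0070 in batch 3. For the 507 lower genes the medians were -0.019 and 0.011.

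For ENSMUSG00000019987 the limma adjusted p (Benjamini-Hochberg) was 0.917 in the model of all arrays, 0.0351 in batch 2 alone, 0.0229 there with postnatal day as a block and 0.00288 with only the TR and HE arrays, with 0.00288 to 0.9999 over 25 alternatives. The score difference had an exact permutation p of 0.595 over 400 arrangements within batches, and of 0.525 over 160 arrangements that keep same-day pairs in batch 2. Batch 2 alone gave 2 changed genes, both higher in TR, and 9 with postnatal day as a block, 3 higher and 6 lower, and batch 3 alone gave 0 with 436 at an unadjusted p under 0.05 in limma. The fit of the TR and HE arrays alone gave 1 gene.

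The comparison of HE with WT asks whether loss of 1 allele alters the tissue. ENSMUSG00000019987 was 5.96-fold higher in HE, at 2.57 ± 0.191 log2 (SE, 6 arrays per group), and was the only gene that changed. ENSMUSG00000030711 differed by 0.04 ± 0.240, ENSMUSG00000044338 by -0.12 ± 0.359 and ENSMUSG00000037071 by -0.06 ± 0.206. The 406 and 507 genes set apart in batch 1 differed between HE and WT in batch 3 by medians of 0.0079 and -0.021 log2. The signature score differed by 0.034, with a 90% interval of -0.17 to 0.25.

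The limma adjusted p (Benjamini-Hochberg) was 1.92e-08 for ENSMUSG00000019987, and the next gene had 0.997. At an unadjusted p under 0.05, 771 genes passed in limma, fewer than the 903 of chance. The score had an exact permutation p of 0.7. The count was 2 with only the HE and WT arrays, 5 with batch as a random block and 0 in limma when the dimmer 50% of genes, among them ENSMUSG00000019987, were left out (337 at an unadjusted p under 0.05).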

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

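The tests of batch, of precision and of a shared origin, and all 3 tests on ENSMUSG00000019987 were chosen only after the results were seen, and the arrangements of labels within batches were added after the counts of genes and before their own values were seen. One array stood apart from its group. On the first principal component of all genes, which held 17.8% of the variance, KO replicate 1 scored -27.99 and the other 5 KO arrays -11.55 to -5.03. It lies on the KO side, since the group means were -11.98 in KO and 10.19 in WT. In all, 32 sets of 6 arrays were examined over 8 measures, and chance alone would set 1.6 apart.

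The change between KO and WT was weighed first. Chance labels are an unlikely source of the count, since 1 of 100 splits of the 12 arrays, the real one, gave 1439 genes (highest other 410). The same held for 1 of 100 arrangements within batches (highest other 715). The splits were drawn from 462 and mix batches, and the arrangements were drawn from 200. A difference of 1 batch would on average leave about 50% of the batch 1 genes with the same sign in batch 3, where 88.5% had it. Of all genes 58.7% had it, and a chance spread of the share was not computed. No KO array carried the count, which stayed at 1036 or more when any 1 of them was left out. A younger state of the KO tissue stays open, since the slope of genes over age in batch 2 correlated with KO minus WT in batch 3 at 0.062 across genes (exact permutation p 0.5 over 36 arrangements of the ages), while 348 of the 507 genes lower in KO and 195 of the 406 genes higher in KO had a slope above 0 in batch 2.

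For the closeness of TR to WT, the change between TR and KO was tested first, and 1 of 100 free splits reached its 561 genes (highest other 220), but these splits mix batches. Exchanging TR and KO labels only within batch 3 allows 20 arrangements, too few for a share under 0.05, of which 1 reached 561 (highest other 4). The count was 31 with only these 12 arrays. It was 0 with batch as a random block, a setting that sets levels of different batches against each other. TR against KO, which has the same arrays per batch, called 561 genes, so differences could be called with this design. The genes called in KO against WT had medians of 0.34 and -0.31 log2, and 150 higher and 135 lower ones reached 0.5 log2. For TR against WT, simulated shifts of 0.5 log2 were called in 66 of 100 genes. Whether low precision hid differences between TR and WT, also of the median KO size, stays open. An adjustment for batch that took the KO signature out of TR arrays would act alike on all arrays of batch 3, where the lowest KO score lay 0.38 above the highest TR score. The KO samples of batch 3, whose title letters differ from those of the other groups, may share an origin. If unrelated to the batch 1 difference, it would on average leave about 50% of the genes called in batch 1 reversed in TR minus KO. Genes are not independent, and a chance spread of that share was not computed. For TR minus HE in batch 2, which holds no untreated knockout, 63.05% of the higher and 55.82% of the lower genes were below 0. In TR minus KO 87.9% of the higher genes were reversed, and 85.4% of the lower genes. At most this argues against an unrelated origin as the whole cause in these genes. An origin that acts along the batch 1 difference, or causes part of it, cannot be told apart from KO in batch 3. It stays open for all genes, as does an effect of the treatment.

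For ENSMUSG00000019987, weighed last, exchanged labels between WT and a group with a knockout allele would place a WT array among the others, but the gap was 1.53 log2. The gene was picked as the only gene called in HE against WT, a choice that favours a gap to WT. An exchange between HE and KO in batch 3 cannot be told apart, since 2 arrays lie in the other group's range on this gene and KO replicate 2 (-0.42) lay below HE replicate 1 (-0.36) by the slope score, and the arrays also overlap on ENSMUSG00000044338 (highest KO 9.84, lowest HE 9.60). Against it, looked at later and with the values known, the lowest KO array lay 0.279 above the highest HE array by the signature score (pooled SD 0.270), and the groups lay apart on ENSMUSG00000030711 (lowest KO 8.26, highest HE 7.25) and ENSMUSG00000037071 (highest KO 9.51, lowest HE 10.17), genes named for their change in KO over arrays that include these. The disease state would place TR near WT, but TR was 2.996 higher than WT in batch 3. The gene may follow the knockout allele itself, as a hypothesis, and linked sequence from another strain or probes on an altered transcript stay open and were not tested.

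For TR against WT, with 1 changed gene, 2 of 100 free splits gave as many (highest other 1), and for HE against WT, with 1 changed gene, 1 of 100 did (highest other 0). Those splits mix batches, and the 20 arrangements within batch 3 are too few for a share under 0.05, with 3 as large in TR against WT (highest other 3) and 1 in HE against WT (highest other 0). For TR against HE the real count was 0, which all 100 splits reach by construction (highest other 1), so they decide nothing.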

How the results depend on the processing

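The slope score, the fit without KO replicates 1 and 4 and the settings that use postnatal day as a block or pair were chosen after seeing the data. Over the settings tried, the count stayed within 1.5 times for KO against WT in 21 of 26, TR against KO in 16 of 25, TR against WT in 20 of 24, TR against HE in 23 of 26 and HE against WT in 21 of 24. No named gene with a call reversed its sign. Without a batch term TR against KO gave 28 genes and TR against WT 2, and with batch as a random block (estimated correlation -0.081) TR against KO gave 0, TR against WT 5 and HE against WT 5. Both settings set levels of different batches against each other, which the apparent adjustment for batch makes not comparable. In TR against KO ENSMUSG00000030711 then differed by -1.11 and -0.97, against -1.60 in the main model. Whether this alone moved the counts was not tested. Counts were lower in batch 3 alone (KO against WT 176, TR against KO 185), in batch 1 alone (KO against WT 913) and with the arrays of the 2 groups alone (KO against WT 904, TR against KO 31), and the cause was not tested. Nor was it for the 2 genes of TR against HE in batch 2 alone, the 9 in batch 2 alone with day as a block, or for 1 gene in TR against HE and 2 in HE against WT with the arrays of the 2 groups alone. Leaving out the dimmer 50% of genes gave 0 in TR against WT and 0 in HE against WT, because ENSMUSG00000019987 is among them. Leaving out KO replicates 1 and 4 gave 925 genes in KO against WT and 297 in TR against KO. Leaving out 1 array at a time gave 949 to 1709 genes in KO against WT, 278 to 680 in TR against KO, and 1 to 2 in TR against WT. With 50 genes each way the score differed by 1.04 in KO against WT and -1.08 in TR against KO, and as a slope over all genes by 0.38 and -0.35, on another scale by construction. The correlation of KO minus WT between batches was 0.49 among genes above the median mean, and the cause was not tested. The fit with batch and postnatal day as a block gave 1493 genes in KO against WT, 624 in TR against KO, 1 in TR against WT, 0 in TR against HE and 1 in HE against WT, and changed no call of a named gene. Not run were the covariate for sex, the other rules for probe sets and the tests of gene lists, since IDs are not paired with names and the table holds 1 value per gene. Background signal is not part of the table, so what dim genes can show was not assessed.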

Other observations

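The model of allele count was added after the data were seen. With the number of knockout alleles (0 in WT, 1 in HE, 2 in KO and TR) and the untreated knockout state as terms, limma called 2 genes for the alleles, 1 higher and 1 lower with more alleles, and 597 for the untreated knockout, 282 higher and 315 lower. One was ENSMUSG00000019987, with a limma adjusted p (Benjamini-Hochberg) of 5.83e-06. On the log2 scale its steps were unequal, at 2.36 from WT to HE and 0.37 from HE to KO in batch 3, where HE and KO arrays overlapped. From HE to TR, which also carries 2 knockout alleles, the step was 0.75 in batch 2 and 0.64 in batch 3. Whether the steps of this gene are equal on the linear scale was not tested. The other gene fell by 0.37 log2 per allele, with a limma adjusted p (Benjamini-Hochberg) of 0.0432.

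Slopes of genes over the 3 postnatal days were set against each other in batches 1 and 2, with no test of single genes. They correlated at Pearson r = 0.326 and Spearman rho = 0.311 across genes, which are not independent replicates. Of the 507 genes lower in KO in batch 1, 348 (68.6%) had a slope above 0 in batch 2, at a median of 0.045 log2 per day, against a median of -0.0022 over all genes. Of the 406 genes higher in KO, 195 (48.0%) had a slope above 0. The slope in batch 2 correlated with KO minus WT in batch 1 at -0.228 (exact permutation p 0.222, adjusted 0.417 over 3 correlations), the slope in batch 1 correlated with KO minus WT in batch 3 at 0.116 (exact permutation p 0.278, adjusted 0.417), and the slope in batch 2 with batch 3 at 0.062 (exact permutation p 0.5, adjusted 0.5).

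The spread of the signature score in batch 3 was 0.358 in KO (SD, n = 3), and the largest of the other groups was 0.131. The difference between the spreads was not tested.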
